A study of Homo sapiens with 12 samples.

How the data were processed

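RNA was measured by sequencing in 12 libraries of BPH1, an epithelial cell line established from benign prostatic hyperplasia. The cells were wild type or knocked out for CHD1, which encodes a chromatin-remodelling ATPase, and were given DMSO (the solvent control) or alisertib, an inhibitor of Aurora kinase A. The alisertib dose was 10 µM and the exposure 24 h. Each of the 4 groups held 3 replicates. Polyadenylated RNA was made into strand-specific libraries. The labels give triplicates without saying whether these were separate cultures, so every p-value below measures only the spread between these samples.

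The deposited table held signal values: read counts per gene that the authors had divided by 1 size factor per library. Multiplying each library by a single factor returned whole reads for every gene, within 0.001 of a read. Median-of-ratios size factors computed anew from those whole reads equalled the factors (largest ratio 1). The labels name TopHat2 2.0.10, HTSeq 0.6.0 and DESeq 1.18.0 and the genome build hg38, without giving the role of each. They do not name the gene annotation release. The table lists 18270 genes, each with at least 10 reads in at least 1 library. Gene positions came from GENCODE 29 on the same build, where 18019 of the gene identifiers were found; positions were used for coordinates and for bins along chromosomes only. The recovered reads per library ranged from 24826940 to 31160825. The deposited table holds no mitochondrially encoded gene. Genes on chromosome Y were not named among the largest changes and were left out of the bins along chromosomes.

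Values were transformed as log2(value + 1), and genes with a mean of at least 10 in at least 1 group were tested, which left 16825. The plan made before the data were examined used a count test for raw counts and limma for normalised values; since the values were normalised, limma 3.58.1 (with trended and robust variance) was the test throughout. All 12 libraries entered 1 model with 4 group means and no other term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 5 comparisons were alisertib against DMSO in wild type, the same in knockout, knockout against wild type in DMSO, the same in alisertib, and the interaction, which is the alisertib effect in knockout minus that in wild type. All log2 fold changes are differences of group means of log2(value + 1), so they are smaller than the ratio of means for genes with few reads. On simulated data with 200 changed genes among 16825, the test of alisertib in wild type recovered 64% of changes of 1.25-fold, 78% of 1.5-fold, 90% of 2-fold and 96% of 4-fold, and called 14 of 16625 unchanged genes. For the interaction the shares were 56%, 74%, 80% and 92%, with 10 unchanged genes called. Each share is of 50 changed genes. The simulated changes lay in 1 group and were far fewer than the 7893 and 2107 genes called in the data. The adjusted threshold depends on that number, so the shares hold for the simulated setting only.

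Gene lists were fixed before the data were examined: 22 lists with 543 genes, of which 3 stand in more than 1 list. The lists with at least 5 tested members, 21 of them, were compared with all other genes by camera with a preset inter-gene correlation of 0.01, and p was adjusted over the lists of a comparison. Counts of called members adjusted over the list alone are given wherever they differ from those adjusted over all tested genes. The same test was run with an estimated correlation, and fry, which asks whether the genes of a list move in 1 direction on balance, was run beside it. The list of mitochondrially encoded genes had no tested member and was not analysed here.

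Named genes followed a rule set before the data were examined. CHD1 and AURKA were always named. Next came the 8 largest increases and the 8 largest decreases by log2 fold change among called genes that had an annotated symbol other than a clone or locus name, a mean of at least 10 in the higher group and no overlap between the values of both groups; for knockout against wild type in alisertib the number was 5 each. For the interaction the rule on overlap was replaced by a mean of at least 10 in the highest group. Last came up to 4 called members of each list with the smallest adjusted p. Some genes that this rule would name are not reported here. Where a group held no read of a gene, its fold was bounded against a floor of 3 reads over the group; where it held 1 to 3 reads, the ratio is given with its exact 95% interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

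Positional structure was described by the median log2 fold change of the tested genes in bins of 10 Mb with at least 20 genes, and by the correlation between neighbouring bins. Alternatives covered the pseudocount, the filter, the scaling, the variance model, a replicate block, thresholds, count tests on the recovered reads (edgeR 4.0.16 and DESeq2 1.42.0, in R 4.3.3), the set test, and the removal of each library in turn. A correction for position, the removal of genes in shifted regions and the CHD family list without CHD1 were chosen after seeing the data.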

Results

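Gene expression was measured by RNA sequencing in BPH1 prostate epithelial cells, wild type or knocked out for the chromatin remodeller CHD1, after 24 h with DMSO or 10 µM alisertib. The question was whether CHD1 alters how cells respond to alisertib, an inhibitor of Aurora kinase A, the mitotic kinase encoded by AURKA. Only the 10 µM dose was given, and no other inhibitor. Effects of alisertib on other targets were therefore not separated from inhibition of Aurora kinase A. Each of the 4 groups held 3 libraries, 12 in all, with 24826940 to 31160825 reads per library over 18270 listed genes. Values are normalised read counts, given as mean ± SD of 3 replicates, and 16825 genes were tested with limma. For gene lists the p is that of the set test, and where a list was called a second p follows that uses an estimated correlation. Counts marked alone were adjusted over the list alone. The first principal component held 58.1% of the variance and separated knockout from wild type, and the second held 17.3% and separated alisertib from DMSO.

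CHD1 (ENSG00000153922.11, chromosome 5, 98853985 to 98928957 on hg38) was lower in every knockout library than in every wild-type library. In DMSO its normalised read count was 2728 ± 107 in wild type and 843 ± 26.9 in knockout, and in alisertib 2481 ± 118 and 681 ± 49.6. The wild-type DMSO libraries read 2670, 2851 and 2663, the knockout DMSO libraries 813, 865 and 851, the wild-type alisertib libraries 2468, 2369 and 2605, and the knockout alisertib libraries 737, 643 and 664. The knockout thus held 30.9% of the wild-type level in DMSO and 27.5% in alisertib (log2 fold changes -1.69 (SE 0.049) and -1.86 (SE 0.049), adjusted p = 2.9e-28 and 1.2e-29). AURKA (ENSG00000087586.17, chromosome 20, 56369389 to 56392337) read 4455 ± 22.02 in wild type in DMSO, 4524 ± 114 in wild type in alisertib, 4912 ± 196 in knockout in DMSO and 4961 ± 77.4 in knockout in alisertib. Its knockout difference was 0.14 on the log2 scale in DMSO (SE 0.034, adjusted p = 4.6e-04) and 0.13 in alisertib (adjusted p = 8.7e-04). AURKA lies in a stretch of chromosome 20 where the median gene was higher in knockout. Once the median of its 10 Mb neighbours was subtracted, its difference in DMSO was -0.21 (adjusted p = 1.2e-06). The p of a gene after such a subtraction takes the subtracted median as exact and covers only the spread between libraries. From 50 to 70 Mb the quartiles of the difference in DMSO were 0.13 and 0.65, so AURKA was not unusual among its neighbours. The adjusted p of its alisertib effect was 0.62 in wild type and 0.77 in knockout.

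**Figure D1:**
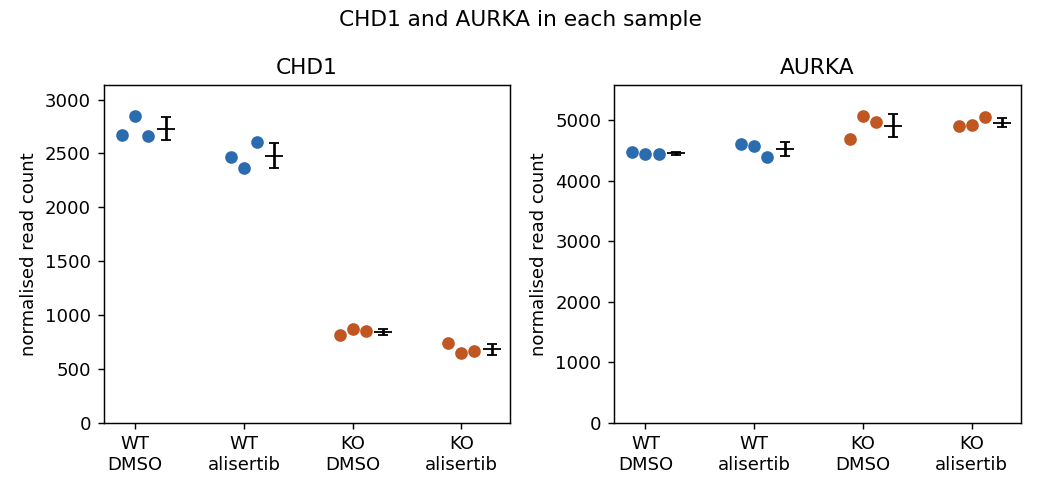
Normalised read counts of CHD1 and AURKA in the 12 libraries, by genotype and treatment, with axes starting at 0; points are libraries, and lines with bars give the mean and SD of 3 replicates. CHD1 averaged 2728 in wild-type and 843 in knockout cells in DMSO, while AURKA averaged between 4455 and 4961 in all 4 groups.

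Alisertib in wild-type cells raised hypoxia and glycolysis genes and lowered MYC target and YAP/TEAD target genes. Interferon-stimulated genes rose and DNA replication and mitotic genes fell by the preset correlation only. Of 24 hypoxia and glycolysis genes, 22 rose and 1 fell (22 higher and 2 lower alone), with a median log2 fold change of 0.74 (adjusted p = 2.0e-18 and 0.0094). BNIP3, a mitophagy receptor, went from 2724 ± 84.1 to 7013 ± 291 (log2 fold change 1.36 (SE 0.035)), and EGLN3, a prolyl hydroxylase that acts on hypoxia-inducible factor, from 684 ± 66.96 to 1779 ± 23.3. SLC2A1, which encodes the glucose transporter GLUT1, rose by 0.78 on the log2 scale. NDRG1, which stands in both the hypoxia and the androgen-response list, rose from 4596 ± 355 to 21324 ± 989.8. Of 40 interferon-stimulated genes, 38 rose and 0 fell, with a median of 0.61 (adjusted p = 7.0e-18 and 0.10). Among them CXCL10, a chemokine, went from 25.04 ± 10.9 to 134 ± 27.8, XAF1 from 1704 ± 165 to 3237 ± 188, and STAT2, a transcription factor of the interferon response, from 1427 ± 94.5 to 2194 ± 98.01. NF-kB and inflammatory genes were higher in 20 and lower in 3 of 33 (21 higher and 3 lower alone), with a median of 0.24 (adjusted p = 1.6e-05 and 0.020). SOD2, the mitochondrial superoxide dismutase, rose by 0.79 on the log2 scale and the collagenase MMP1 by 1.30, whereas the chemokine CXCL1 fell by 0.82. Antigen presentation genes were higher in 15 and lower in 1 of 18 (adjusted p = 1.4e-05 and 0.10). HLA-F rose by 0.56 and the peptide transporter gene TAP2 fell by 0.38.

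Among growth and division genes in wild-type cells, the MYC target and ribosome biogenesis list moved most: 26 of 28 genes fell and 0 rose, with a median log2 fold change of -0.54 (adjusted p = 1.1e-22 and 0.020). The nucleolar gene NOP56 went from 9646 ± 191 to 5779 ± 81.6, and BOP1, needed for the large ribosomal subunit, from 7679 ± 271 to 4656 ± 92.3. Of 38 DNA replication and G1/S genes, 27 fell and 2 rose (3 higher and 27 lower alone), with a median of -0.18 (adjusted p = 3.8e-07 and 0.10). The nucleotide synthesis genes TK1 and RRM2 changed by -0.43 and -0.45. Of 37 mitotic genes, 23 fell and 2 rose, with a median of -0.15 (adjusted p = 1.2e-05 and 0.17). CDC20, an activator of the anaphase-promoting complex, went from 11171 ± 237 to 8063 ± 400.1, and TPX2, the spindle protein that activates Aurora kinase A, changed by -0.32. Homologous recombination and Fanconi genes were lower in 12 and higher in 3 of 29 (adjusted p = 0.010 and 0.17), with FANCI at -0.36 and RAD54L at -0.54. Histone genes were lower in 9 and higher in 2 of 17 (adjusted p = 0.016 and 0.10), with H2AZ1 at -0.38. Of 25 YAP/TEAD targets, 18 fell and 1 rose (3 higher and 18 lower alone), with a median of -0.35 (adjusted p = 4.4e-08 and 0.011). ANKRD1 went from 228 ± 28.4 to 48.4 ± 7.28 and CCN1, a matricellular protein gene, from 2757 ± 39.2 to 1272 ± 14.3.

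The p53 target and cholesterol biosynthesis lists rose in wild-type cells as well. By the preset correlation only, stress response, mesenchymal and lysosome genes rose too. Of 26 p53 targets, 14 rose and 4 fell (15 higher and 4 lower alone, adjusted p = 0.0035 and 0.032). The cyclin-dependent kinase inhibitor CDKN1A went from 4727 ± 147 to 8636 ± 234 and MDM2, which targets p53 for degradation, from 2694 ± 126 to 4327 ± 156, while PLK2, a polo-like kinase gene, fell by 1.20 on the log2 scale. Cholesterol biosynthesis genes were higher in 16 and lower in 4 of 24 (17 higher and 4 lower alone, adjusted p = 7.7e-06 and 0.0094), with INSIG1, a sterol sensor, at 0.77. Unfolded protein and integrated stress response genes were higher in 15 and lower in 3 of 25 (adjusted p = 0.0072 and 0.17). The chaperone gene HSPA5 rose by 0.43 and the serine synthesis gene PSAT1 fell by 0.45. Mesenchymal and fibroblast genes were higher in 12 and lower in 3 of 20 (adjusted p = 0.010 and 0.061), with the collagen gene COL5A1 at 0.89 and N-cadherin (CDH2) at -1.09. Lysosome and autophagy genes were higher in 12 and lower in 6 of 27 (adjusted p = 0.022 and 0.084, and 0.088 after median centring). The lists that did not pass were the BCL2 family (7 higher and 3 lower of 16), luminal (7 and 4 of 17, or 8 and 4 alone), basal (10 and 8 of 24, or 11 and 8 alone), neuroendocrine (2 and 0 of 10), immune and endothelial (2 and 0 of 5, or 3 and 0 alone) and CHD family genes (4 and 3 of 10, or 4 and 4 alone). BMF, which encodes a pro-apoptotic BH3-only protein, nevertheless went from 148 ± 21.1 to 408 ± 22.4.

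In all, 7893 genes differed between alisertib and DMSO in wild-type cells, 3913 higher and 3980 lower, and 707 of them changed at least 2-fold, 578 higher and 129 lower. The largest increases included EGR2, an immediate early transcription factor gene, from 1.44 ± 0.644 to 25.2 ± 2.65 (adjusted p = 5.5e-08), STC1, which encodes stanniocalcin, from 7.53 ± 1.86 to 71.4 ± 7.78, TCIM from 6.05 ± 1.35 to 54.5 ± 4.77, and the matrix gene MXRA5 from 11.04 ± 2.05 to 82.5 ± 4.26. PNLDC1, with 2 reads over the DMSO group and 36 over the alisertib group, was 16.8-fold higher (95% interval 4.33 to 144). The largest decreases included FST, the activin antagonist follistatin, from 3465 ± 265 to 793 ± 55.5 (adjusted p = 4.4e-14), SLC7A14 from 50.4 ± 5.22 to 9.73 ± 1.67, and ADAMTSL1 from 51.4 ± 3.53 to 12.96 ± 5.57. CHD1 itself changed by -0.14 (SE 0.049, adjusted p = 0.020), a call that was lost without trended variance (0.092) and without wild-type alisertib replicate 1 (0.057), replicate 2 (0.13) or wild-type DMSO replicate 2 (0.13). With values centred on each library's median the balance of directions moved to 3111 higher and 5063 lower, and with upper-quartile scaling in edgeR to 4485 higher and 3406 lower.

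Alisertib in knockout cells lowered MYC target, DNA replication and YAP/TEAD target genes and raised stress response and hypoxia genes. Of 25 unfolded protein and integrated stress response genes, 21 rose and 1 fell, with a median log2 fold change of 0.40 (adjusted p = 2.3e-15 and 0.014). DDIT3, the stress transcription factor CHOP, went from 264 ± 12.4 to 601 ± 37.9, HERPUD1 from 1273 ± 80.02 to 1999 ± 97.6, and HSPA5 from 26005 ± 853 to 36055 ± 668. Of 24 hypoxia and glycolysis genes, 19 rose and 0 fell (21 higher and 0 lower alone), with a median of 0.32 (adjusted p = 2.2e-16 and 0.014), and BNIP3 went from 4575 ± 125 to 7149 ± 151. Of 33 NF-kB and inflammatory genes, 22 rose and 3 fell (22 higher and 4 lower alone, adjusted p = 1.8e-06 and 0.014), with SOD2 at 0.65 and the chemokine CCL20 at 1.57. Of 26 p53 targets, 11 rose and 3 fell (adjusted p = 0.0017 and 0.023). MDM2 changed by 0.77 and GDF15, a stress cytokine, went from 49.95 ± 7.87 to 164 ± 18.4. Of 40 interferon-stimulated genes, 14 rose and 1 fell, with a median of 0.13 (adjusted p = 8.4e-05 and 0.38), and CXCL10 went from 12.8 ± 2.87 to 40.3 ± 4.59.

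The MYC target list fell in knockout cells in 26 of 28 genes and rose in 0 (1 higher and 26 lower alone), with a median of -0.36 (adjusted p = 2.2e-21 and 0.023). UTP20, a ribosomal RNA processing gene, changed by -0.58. DNA replication and G1/S genes fell in 30 of 38 and rose in 0 (0 higher and 31 lower alone), with a median of -0.21 (adjusted p = 1.8e-14 and 0.023), and RRM2 went from 6635 ± 225 to 4689.6 ± 61.7. Mitotic genes fell in 21 of 37 and rose in 3 (3 higher and 22 lower alone), with a median of -0.13 (adjusted p = 2.0e-04 and 0.25). AURKB, the gene of Aurora kinase B, changed by -0.38 and HMMR, a spindle-associated receptor gene, by 0.30. Homologous recombination and Fanconi genes fell in 17 of 29 and rose in 1 (1 higher and 18 lower alone, adjusted p = 4.0e-05 and 0.067), with EXO1 at -0.40. YAP/TEAD targets fell in 15 of 25 and rose in 1 (adjusted p = 5.8e-07 and 0.014), with F3, the tissue factor gene, at -0.57. Histone genes fell in 7 of 17 and rose in 2 (2 higher and 8 lower alone, adjusted p = 0.013 and 0.11). Basal epithelial genes fell in 13 of 24 and rose in 7 (7 higher and 14 lower alone, adjusted p = 0.013 and 0.25, and 0.054 among genes with a mean of at least 50). The keratin gene KRT14 went from 3336 ± 147 to 2173 ± 126. Antigen presentation genes rose in 8 and fell in 4 of 18 (8 higher and 5 lower alone, adjusted p = 0.040 and 0.38), a call lost after median centring (0.083), without knockout alisertib replicate 2 (0.054) and without knockout DMSO replicate 3 (0.060).

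Lists that did not pass in knockout cells were the BCL2 family (6 higher and 4 lower of 16), luminal (4 and 3 of 17), mesenchymal and fibroblast (4 and 3 of 20), neuroendocrine (1 and 0 of 10), immune and endothelial (2 and 0 of 5), CHD family (2 and 3 of 10), lysosome and autophagy (9 and 4 of 27) and cholesterol biosynthesis genes (3 and 7 of 24, or 3 and 9 alone). In total 5834 genes differed, 2588 higher and 3246 lower, and 280 changed at least 2-fold, 236 higher and 44 lower. The largest increases included IFITM10 from 5.25 ± 0.641 to 40.3 ± 5.62 (adjusted p = 1.6e-08), EGR2 from 1.93 ± 0.873 to 18.2 ± 7.60, and NUPR1, a stress-induced transcriptional regulator gene, from 19.3 ± 3.09 to 94.03 ± 18.3. LCT, the lactase gene, had no read in the DMSO group and was at least 11.6-fold higher in alisertib. The largest decreases included DKK1, a secreted inhibitor of WNT signalling, from 6279.7 ± 556 to 2468 ± 45.1 (adjusted p = 3.1e-10), the extracellular matrix gene RELN from 217 ± 13.4 to 84.7 ± 8.48, and ANKRD1 from 271 ± 33.4 to 81.8 ± 8.88. The balance of directions moved to 2188 higher and 3831 lower with median centring, and to 3371 higher and 2624 lower with upper-quartile scaling in edgeR.

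**Figure D2:**
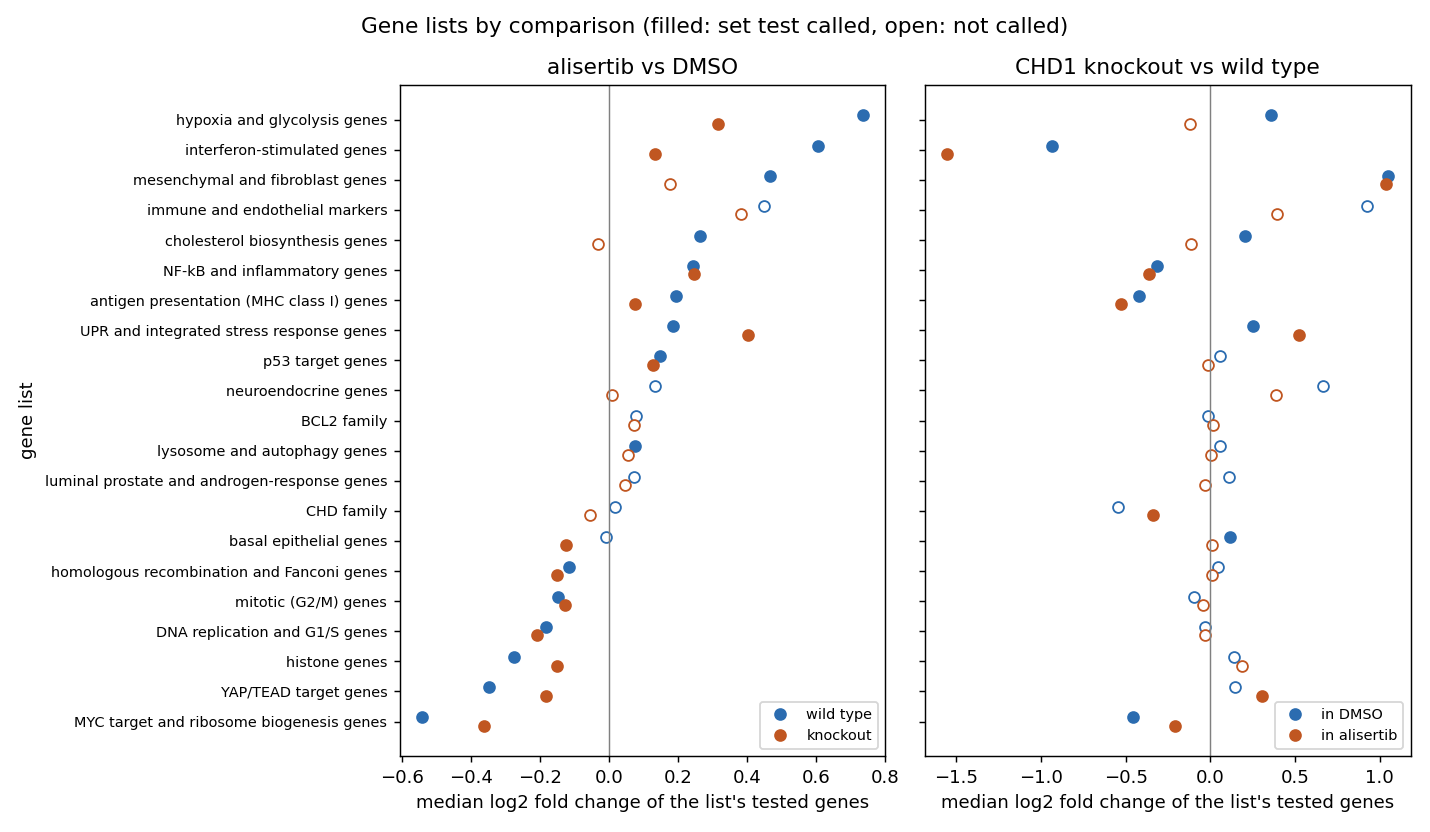
Median log2 fold change of the tested members of 21 gene lists, on the left for alisertib against DMSO in wild type and knockout, on the right for knockout against wild type in DMSO and in alisertib. Filled points mark lists called by camera with the preset correlation and open points those not called. Hypoxia and glycolysis genes stand at 0.74 under alisertib in wild type and 0.32 in knockout, and interferon-stimulated genes stand at -0.93 in knockout against wild type in DMSO.

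The interaction asked directly whether the response to alisertib differed between genotypes. Hypoxia and glycolysis, cholesterol biosynthesis and basal epithelial genes responded lower in knockout than in wild type, and stress response genes responded higher. In DMSO the lower-responding lists stood higher in knockout by the preset correlation only, with medians of 0.36, 0.21 and 0.12 against wild type in that order. With an estimated correlation the adjusted p were 0.33, 0.084 and 0.33. In alisertib their medians were -0.12, -0.12 and 0.01, none of them called. The interaction uses the same DMSO libraries, so a higher start and a lower response are not independent results. By the preset correlation only, interferon-stimulated genes responded lower and MYC target genes higher. Of 24 hypoxia and glycolysis genes, 14 had a lower and 2 a higher response in knockout (2 higher and 17 lower alone), with a median interaction of -0.39 (adjusted p = 2.8e-18 and 0.0097). BNIP3 had an interaction of -0.72 (SE 0.049) and the pH regulator CA9 of -0.64 (SE 0.053). Of 24 cholesterol biosynthesis genes, 15 were lower and 0 higher (0 higher and 17 lower alone), with a median of -0.27 (adjusted p = 1.0e-15 and 3.4e-04). Of 40 interferon-stimulated genes, 21 were lower and 0 higher (0 higher and 26 lower alone), with a median of -0.40 (adjusted p = 6.8e-20 and 0.12). SAMD9 had an interaction of -0.48. Of 24 basal epithelial genes, 13 were lower and 0 higher (0 higher and 14 lower alone, adjusted p = 1.8e-10 and 0.035), and KRT14 went from 3924 ± 220.4 to 4398 ± 89.3 in wild type against 3336 ± 147 to 2173 ± 126 in knockout. Antigen presentation genes were lower in 9 of 18 and higher in 0 (1 higher and 10 lower alone, adjusted p = 3.5e-05 and 0.15), with the peptidase gene ERAP2 at -0.32.

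MYC target genes had a higher interaction in 19 of 28 and a lower one in 0 (21 higher and 0 lower alone), with a median of 0.20 (adjusted p = 2.0e-13 and 0.070). NPM1, the nucleolar protein nucleophosmin, had 0.31. In each genotype 26 of the 28 fell, with a smaller median change in knockout (-0.36) than in wild type (-0.54). Unfolded protein and integrated stress response genes were higher in 13 and lower in 0 of 25 (13 higher and 2 lower alone), with a median of 0.19 (adjusted p = 1.8e-08 and 0.039). PSAT1 went from 4669 ± 127 to 3409 ± 91.4 in wild type and from 5944 ± 42.1 to 6493 ± 149 in knockout, DDIT3 had an interaction of 0.90 (SE 0.11), and the cystine transporter gene SLC7A11 had 0.45. YAP/TEAD targets were higher in 7 and lower in 1 of 25 (10 higher and 1 lower alone, adjusted p = 1.6e-04 and 0.049), with CCN1 at 0.39. Mitotic genes were higher in 6 and lower in 0 of 37 (9 higher and 1 lower alone), with a median of 0.05 (adjusted p = 0.016 and 0.48). The call was lost without knockout alisertib replicate 3 (0.066), knockout DMSO replicate 1 (0.14) or wild-type DMSO replicate 2 (0.060). CDC20 had an interaction of 0.32 and PTTG1, the securin gene, of 0.34. Mesenchymal and fibroblast genes were lower in 6 and higher in 1 of 20 (adjusted p = 0.035 and 0.11), a call lost without wild-type alisertib replicate 2 (0.080) or replicate 3 (0.064) and among genes with a mean of at least 50 (0.070). In other lists, the collagenase gene MMP1, from the NF-kB list, went from 349 ± 26.98 to 859 ± 46.2 in wild type. In knockout it went from 4469 ± 130.1 to 3833 ± 112 (interaction -1.52 (SE 0.069)). NDRG1, from the hypoxia and androgen-response lists, had -1.13 (SE 0.080). The lists not called were DNA replication (1 higher and 6 lower of 38, or 1 and 8 alone), homologous recombination (1 and 3 of 29), p53 targets (2 and 3 of 26, or 2 and 5 alone), BCL2 family (0 and 1 of 16), NF-kB (4 and 7 of 33, or 4 and 8 alone), luminal (1 and 4 of 17, or 2 and 4 alone), neuroendocrine (0 and 2 of 10), immune and endothelial (0 and 0 of 5), CHD family (0 and 2 of 10), histone (0 and 1 of 17) and lysosome genes (1 and 4 of 27).

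Across genes, which are not independent replicates, the alisertib effects in the genotypes correlated with Pearson r 0.61 and Spearman rho 0.63 over all 16825 tested genes. Both genotypes called 4456 genes, of which 4351 changed in the same direction and 105 in opposite directions, where chance would give 1370 in the same direction. Among the 9271 genes called in either genotype, the total least squares slope of the knockout effect on the wild-type effect was 0.64, and the SD of the effect over all tested genes was 0.454 in wild type and 0.350 in knockout. The interaction passed the test for 2107 genes, 1001 higher and 1106 lower, of which 129 reached a 2-fold difference, 44 higher and 85 lower. By the fitted effects, 1170 of the 2107 moved the same way in both genotypes and less in knockout. Another 152 moved the same way and more in knockout, and 785 in opposite directions. Many of these signs rest on an effect that was not called. Of the 2107, 822 were called in both genotypes, 978 in wild type only, 275 in knockout only and 32 in neither. At most 105 of the 785 were called in both. Large interactions whose call held in every alternative that tested them included HES7, a transcriptional repressor gene, at 1.91 (SE 0.32), ADAMTSL1 at 1.67 (SE 0.31), STC1 at -2.44 (SE 0.53), the protocadherin gene PCDHGB2 at -2.40 (SE 0.48) and NSG1 at -2.46 (SE 0.57). STC1 went from 5.97 ± 3.06 to 9.70 ± 3.63 in knockout, and HES7 from 86.97 ± 12.8 to 38.6 ± 2.14 in wild type against 15.3 ± 2.83 to 26.4 ± 0.465 in knockout. CHD1 had an interaction adjusted p of 0.11 (0.025 without knockout alisertib replicate 1) and AURKA of 0.95. Median centring moved the balance to 1307 higher and 835 lower, and without trended variance 885 genes passed.

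**Figure D3:**
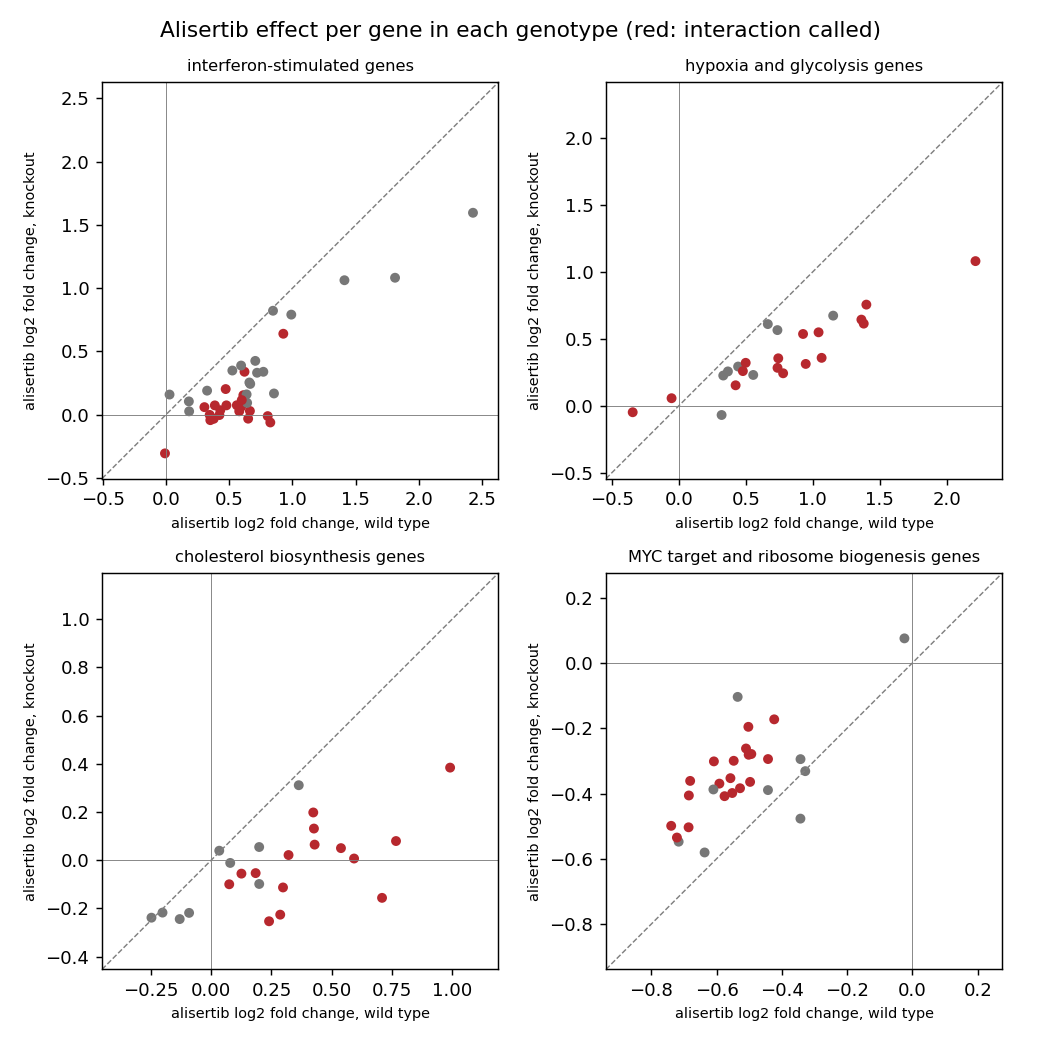
Log2 fold change of alisertib against DMSO in wild type (horizontal axis) and in knockout (vertical axis) for the tested genes of 4 lists, 1 point per gene, red where the interaction was called; the dashed line marks equal effects. Most hypoxia, interferon-stimulated and cholesterol genes lie below the line (median interactions -0.39, -0.40 and -0.27), and most MYC target genes lie above it (0.20).

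Knockout against wild type in DMSO asked what loss of CHD1 changed without the drug. Mesenchymal genes were higher in knockout. Interferon-stimulated, antigen presentation and MYC target genes were lower by the preset correlation only. Of 40 interferon-stimulated genes, 36 were lower and 1 higher, with a median log2 fold change of -0.93 (adjusted p = 2.7e-19 and 0.19). XAF1 read 1704 ± 165 in wild type and 461 ± 23.8 in knockout (log2 fold change -1.88 (SE 0.057)), and HERC6 1470.4 ± 137 and 617 ± 6.08. Antigen presentation genes were lower in 12 and higher in 5 of 18, with a median of -0.42 (adjusted p = 0.0053 and 0.33). HLA-B read 19889 ± 985 and 9152 ± 108, and B2M, the light chain of MHC class I, changed by -0.61. Of 33 NF-kB and inflammatory genes, 21 were lower and 9 higher (adjusted p = 0.0053 and 0.13). The interleukin gene IL1B read 13602 ± 102 and 5762 ± 205, while MMP1 read 349 ± 26.98 and 4469 ± 130.1 and the adhesion gene ICAM1 changed by 1.81. Of 28 MYC target genes, 26 were lower and 1 higher, with a median of -0.46 (adjusted p = 1.5e-12 and 0.13). MYC itself read 12356 ± 164 and 7459 ± 159 (log2 fold change -0.73) in a 10 Mb bin whose median was -0.39, and CDK4, a G1 cyclin-dependent kinase gene, changed by -0.83. Mesenchymal and fibroblast genes were higher in 18 and lower in 1 of 20, with a median of 1.05 (adjusted p = 1.3e-09 and 0.0031). The matrix gene SPARC read 1044 ± 43.7 and 5481 ± 152, the collagen gene COL5A1 515 ± 33.1 and 5388 ± 438, and the cadherin gene CDH11 8.31 ± 2.61 and 322 ± 16.3.

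Further lists called in DMSO were cholesterol biosynthesis (15 higher and 5 lower of 24, adjusted p = 0.0053 and 0.084), hypoxia and glycolysis (14 and 6 of 24, or 14 and 7 alone, adjusted p = 0.0049 and 0.33), unfolded protein and stress response (14 and 7 of 25, adjusted p = 0.027 and 0.33) and basal epithelial genes (14 and 9 of 24, or 14 and 10 alone, adjusted p = 0.027 and 0.33). All of these leaned towards higher expression in knockout: the angiogenic factor gene VEGFA changed by 0.86, the serine synthesis gene PHGDH by 0.68 and the integrin gene ITGA6 by 0.90. Mitotic genes did not pass (6 higher and 18 lower of 37, adjusted p = 0.064), and they did pass once the median of each 10 Mb neighbourhood was subtracted (median -0.16, adjusted p = 0.0014, and 0.33 with an estimated correlation). After that subtraction cholesterol biosynthesis genes passed with the estimated correlation too (adjusted p = 0.025). The other lists not called were DNA replication (12 higher and 15 lower of 38), homologous recombination (8 and 6 of 29), p53 targets (11 and 6 of 26), BCL2 family (6 and 4 of 16), luminal (8 and 6 of 17), neuroendocrine (6 and 2 of 10, or 6 and 3 alone), immune and endothelial (3 and 0 of 5), CHD family (2 and 4 of 10, or 2 and 5 alone, CHD1 among the lower), histone (5 and 4 of 17), lysosome (11 and 11 of 27) and YAP/TEAD genes (10 and 8 of 25). FOXA1, a pioneer factor of luminal prostate cells, read 761 ± 53.9 in wild type and 78.9 ± 10.8 in knockout (log2 fold change -3.26 (SE 0.098)).

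In total 9754 genes differed between the genotypes in DMSO, 4727 higher and 5027 lower in knockout (4373 and 5481 with median centring, 4999 and 4611 with upper-quartile scaling in edgeR), and 1710 differed at least 2-fold, 1105 higher and 605 lower. The largest increases included OLFM4, an olfactomedin family gene, from 3.90 ± 2.55 to 320.0 ± 16.8, MXRA5 from 11.04 ± 2.05 to 609.9 ± 65.2 (adjusted p = 7.6e-33) and TMEM200A from 7.64 ± 5.08 to 451 ± 19.8. FMOD, the gene of the matrix protein fibromodulin, had 3 reads in wild type and was 125-fold higher in knockout (95% interval 42.5 to 609). The largest decreases included VSTM2L from 1413 ± 36.1 to 8.91 ± 6.93 and STRA6, a vitamin A transporter gene, from 458 ± 45.98 to 11.7 ± 2.04. SLC14A1, a urea transporter gene, had no read in knockout and was at least 122-fold lower, and the receptor phosphatase gene PTPRD at least 42.0-fold lower. Neighbouring genes moved together: the medians of adjacent 10 Mb bins correlated with r 0.67, against 0.17 for the alisertib effect in wild type over the same 264 bins. The 138 tested genes in the first 50 Mb of chromosome 5 had a median of 0.85 and 93.5% were higher in knockout, and the medians of the 225 genes in the first 50 Mb of chromosome 8 and the 345 genes from 60 to 150 Mb were -0.47 and -0.42. In 9 such runs of bins, with a median beyond 0.25 in DMSO and beyond 0.2 in alisertib (limits chosen after seeing the data), lay 1803 tested genes. Subtracting the median of the neighbourhood left 9303 genes called, and 8044 of the 9754 kept both their call and their direction. The medians of interferon-stimulated, mesenchymal and MYC target genes were then -1.06, 1.09 and -0.41.

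**Figure D4:**
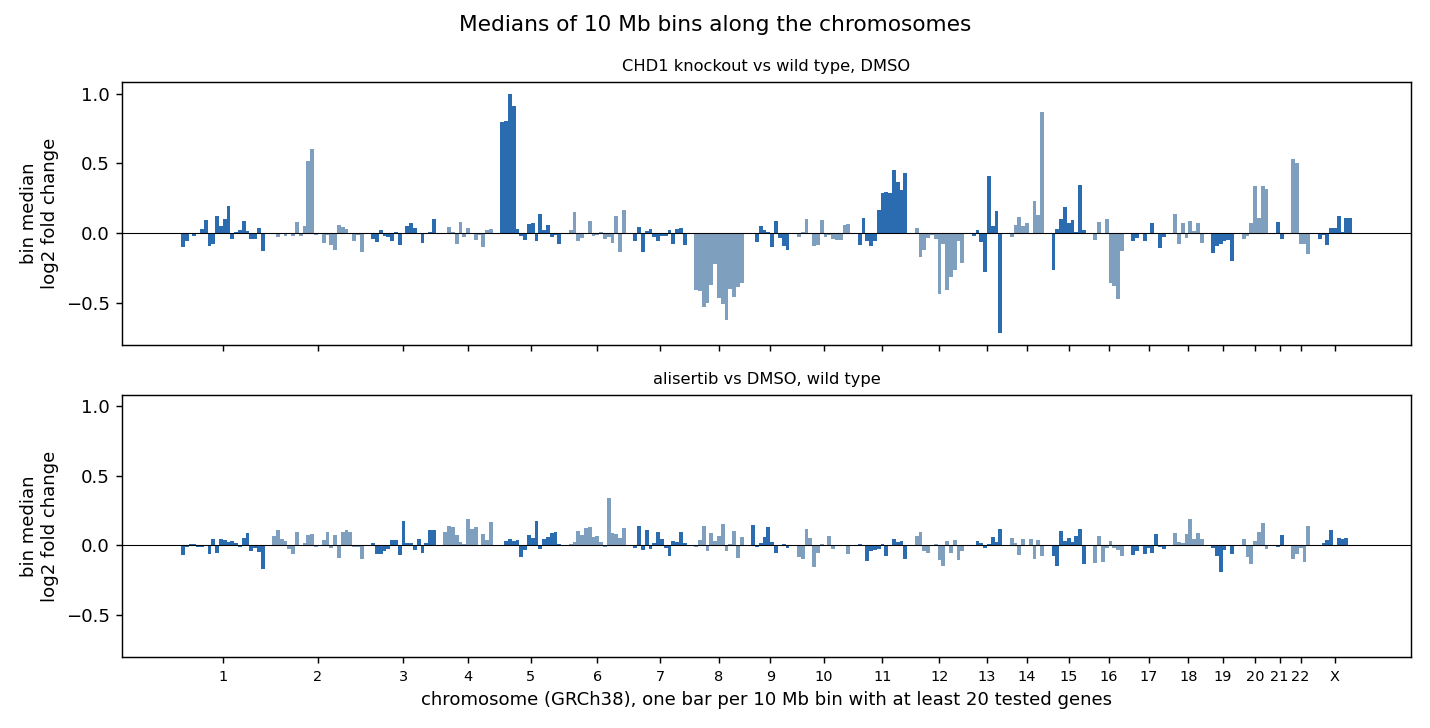
Median log2 fold change of tested genes in 10 Mb bins with at least 20 genes, in order along the chromosomes, for knockout against wild type in DMSO and for alisertib against DMSO in wild type. For the knockout comparison 43 of 264 bins lie beyond 0.25 from 0, many side by side, and for alisertib in wild type 1 does.

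Knockout against wild type in alisertib asked the same under the drug, and 7462 genes were called in both treatments, 7301 of them in the same direction and 161 in opposite directions. Of 40 interferon-stimulated genes, 39 were lower and 0 higher in knockout, with a median of -1.55 (adjusted p = 1.8e-28 and 0.11). SAMD9 read 12144 ± 665 in wild type and 5206 ± 118 in knockout. Antigen presentation genes were lower in 13 and higher in 4 of 18 (adjusted p = 1.9e-05 and 0.20), with HLA-B at -1.24. NF-kB and inflammatory genes were lower in 21 and higher in 5 of 33 (adjusted p = 5.3e-04 and 0.095), with CXCL1 at -0.96. Mesenchymal and fibroblast genes were higher in 16 and lower in 0 of 20, with a median of 1.04 (adjusted p = 6.3e-08 and 0.0058), and CDH2 read 108 ± 17.6 and 540.3 ± 36.6. Unfolded protein and stress response genes were higher in 18 and lower in 3 of 25 (18 higher and 4 lower alone), with a median of 0.52 (adjusted p = 1.1e-06 and 0.095). YAP/TEAD targets were higher in 15 and lower in 6 of 25 (adjusted p = 0.011 and 0.20), with the receptor kinase gene AXL at 1.27. MYC target genes were lower in 24 and higher in 1 of 28 (1 higher and 25 lower alone), with a median of -0.21 (adjusted p = 7.5e-07 and 0.20). CHD family genes, with the knocked-out CHD1 among them, were lower in 5 and higher in 1 of 10 (1 higher and 6 lower alone, adjusted p = 0.011 and 0.20). Without CHD1 the list did not pass (1 higher and 4 lower of 9, median -0.17, adjusted p = 0.081).

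Lists not called in alisertib were mitotic (7 higher and 17 lower of 37), DNA replication (8 and 17 of 38), homologous recombination (8 and 7 of 29), p53 targets (9 and 5 of 26), BCL2 family (5 and 5 of 16), luminal (6 and 6 of 17), basal (11 and 11 of 24), neuroendocrine (4 and 2 of 10), immune and endothelial (2 and 0 of 5), histone (8 and 6 of 17, or 9 and 6 alone), cholesterol biosynthesis (6 and 12 of 24, or 6 and 13 alone), lysosome (7 and 10 of 27) and hypoxia genes (6 and 13 of 24). In total 9385 genes differed, 4506 higher and 4879 lower (4512 and 4843 with median centring, 4940 and 4524 with upper-quartile scaling in edgeR), and 1589 differed at least 2-fold, 901 higher and 688 lower. FMOD read 1.37 ± 1.19 in wild type and 156 ± 3.55 in knockout and TMEM200A 5.05 ± 2.13 and 362 ± 35.02, while VSTM2L read 1498 ± 33.9 and 11.7 ± 2.08. TRIM31, a ubiquitin ligase gene with 3 reads in knockout, was 179-fold lower (95% interval 61.0 to 873). The median, the mean and the test of a list differed in sign for 1 list under alisertib in wild type (basal), 1 in knockout (CHD family), 2 between genotypes in DMSO (BCL2 and lysosome), 4 between genotypes in alisertib (p53, BCL2, luminal and lysosome) and 2 in the interaction (p53 and BCL2), none of them called. Subtracting the median of the neighbourhood left 8897 genes called, and 7680 of the 9385 kept both their call and their direction. Mitotic genes then passed (median -0.11, adjusted p = 0.025 and 0.60), and NF-kB and inflammatory genes passed with the estimated correlation too (adjusted p = 0.046). AURKA then stood at -0.27 in alisertib.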

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

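The reassignment of residuals, the sorting of splits by exchanged labels, the gap between interferon-stimulated and other genes, the subtraction of neighbourhood medians and the limits that define shifted regions were chosen after the data were seen; the other tests below were planned. Each result of the interaction is named here because the alisertib effects of the genotypes differed by a test of the difference itself. The interaction passed for 2107 genes. The lists that passed had median interactions of -0.39 (hypoxia and glycolysis), -0.40 (interferon-stimulated), -0.28 (mesenchymal and fibroblast), -0.27 (cholesterol biosynthesis), -0.14 (basal epithelial), -0.14 (antigen presentation), 0.047 (mitotic), 0.13 (YAP/TEAD targets), 0.19 (unfolded protein and stress response) and 0.20 (MYC targets). With an estimated correlation 5 of these 10 passed: hypoxia, cholesterol, basal, YAP/TEAD and stress response genes.

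Among the largest interactions, HES7 (1.91), ADAMTSL1 (1.67), GRIA1 (-3.42), NSG1 (-2.46), STC1 (-2.44) and PCDHGB2 (-2.40) kept their call in every alternative that tested them. GRIA1 had no read in wild type in DMSO, so the size of its fitted value depends on the pseudocount. The others, with group means of at most 76.8, lost their call in some alternatives: TBCEL-TECTA (2.28, highest adjusted p over the alternatives 0.17), GPBAR1 (2.22, 0.13), LINC01140 (2.03, 0.11), LINC00173 (1.86, 0.11), RPS3AP20 (1.85, 0.11), INHBE (1.67, 0.13), LRRC55 (-3.03, 0.053), LINC01215 (-2.87, 0.12), TREM1 (-2.83, 0.12) and KIRREL2 (-2.40, 0.070). TBCEL-TECTA, GPBAR1 and LINC00173 lost it on removal of any of 8 libraries, RPS3AP20 of 7, LINC01140 of 6, INHBE of 5, KIRREL2 of 4 and LINC01215 of 3. LRRC55 lost it without knockout alisertib replicate 3 (0.053). TREM1 lost it only with a pseudocount of 0.5 and without trended variance. From the called lists came BNIP3 (-0.72), SLC2A1 (-0.54), SAMD9 (-0.48), ERAP2 (-0.32), NLRC5 (-0.29), KRT14 (-0.78), KRT6A (-0.42), COL5A1 (-0.79), SPARC (-0.35), CDC20 (0.32), PTTG1 (0.34), PSAT1 (0.58), SHMT2 (0.43), IGFBP3 (0.35), CCN1 (0.39), NPM1 (0.31) and HSPD1 (0.25). NDRG1 (-1.13) stands in the called hypoxia list and in the androgen-response list, which was not called. From lists that were not called came MMP1 (-1.52), PLK2 (0.53), CTSD (-0.45), ENO2 (-0.40), BRIP1 (-0.29), CHD6 (-0.25), MCM6 (-0.19) and MCL1 (-0.15). Without trended variance NLRC5 (0.069), BRIP1 (0.067), CHD6 (0.058), MCM6 (0.062) and MCL1 (0.083) lost their call. After median centring MCL1 (0.073) did. BRIP1 also lost it without knockout alisertib replicate 2 (0.063) or wild-type alisertib replicate 1 (0.053). MCL1 lost it without knockout alisertib replicate 3 (0.059).

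The adjusted p without each library whose removal ended a call is given here for the genes with few reads, by group and replicate number. TBCEL-TECTA lost its call without knockout alisertib 1 (0.083), 2 (0.082), 3 (0.087), knockout DMSO 3 (0.13), wild-type alisertib 1 (0.068), 2 (0.10) or wild-type DMSO 1 (0.077), 3 (0.17). GPBAR1 lost its call without knockout alisertib 3 (0.070), knockout DMSO 1 (0.091), 3 (0.069), wild-type alisertib 1 (0.13), 2 (0.057), 3 (0.053) or wild-type DMSO 2 (0.12), 3 (0.094). LINC00173 lost its call without knockout alisertib 1 (0.095), 2 (0.065), 3 (0.056), knockout DMSO 2 (0.074), 3 (0.076), wild-type alisertib 2 (0.11) or wild-type DMSO 1 (0.080), 2 (0.063). RPS3AP20 lost its call without knockout alisertib 2 (0.11), 3 (0.071), knockout DMSO 1 (0.061), 2 (0.073), 3 (0.060) or wild-type alisertib 2 (0.086), 3 (0.068). LINC01140 lost its call without knockout alisertib 1 (0.091), 3 (0.092), knockout DMSO 1 (0.083), 3 (0.065) or wild-type alisertib 1 (0.11), 3 (0.077). INHBE lost its call without knockout alisertib 3 (0.070), knockout DMSO 2 (0.063), wild-type alisertib 1 (0.10) or wild-type DMSO 1 (0.053), 2 (0.066). KIRREL2 lost its call without knockout alisertib 2 (0.069), knockout DMSO 1 (0.058), 2 (0.050) or wild-type alisertib 2 (0.057). LINC01215 lost its call without knockout alisertib 2 (0.10), knockout DMSO 1 (0.054) or wild-type DMSO 3 (0.051).

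Differences between knockout and wild type clustered along chromosomes, with a correlation of 0.67 between the medians of neighbouring 10 Mb bins, and none of 1000 shuffles of the bins came as high (highest 0.20). The effect of alisertib in wild type gave 0.17 over the same bins, which argues against the idea that any large expression change clusters as strongly; in knockout it gave 0.32, above every shuffle of the genotype bins, with no bin median beyond 0.20, so weaker clustering also occurs without a genotype difference. A candidate explanation is a difference in copy number between the knockout and wild-type cultures, which predicted a value above 0.3, and whole stretches moved together, such as the first 50 Mb of chromosome 5 (median 0.85), 60 to 150 Mb of chromosome 8 (-0.42) and 70 to 140 Mb of chromosome 11 (0.32). No DNA was measured, so regional regulation by CHD1 stays open, and without a further knockout clone or a rescue the loss of CHD1 and the history of the clone were not separated.

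Interferon-stimulated genes were lower in knockout. The pseudocount only shrinks a difference towards 0, so it could not have made the list lower. Its planned test shows only whether the difference was confined to genes with few reads. Of the 40 genes, 37 had a wild-type mean of at least 100 in DMSO. Their median was -0.91 (95% bootstrap interval -1.51 to -0.74). This interval and those below resampled genes as if independent and leave out the spread between libraries. The listed genes had an estimated correlation of 0.53. The median over all tested genes, -0.010, was set by the scaling and decides nothing about the interferon-stimulated genes. Their list lay below the other genes (gap -0.92, interval -1.53 to -0.74), and 1 factor per library cannot open such a gap. Copy number of the listed genes themselves does not account for it, since a median of -1.06 remained after subtraction of the neighbourhood median (interval -1.49 to -0.74); a copy-number change of a regulator elsewhere was not tested. Loss of CHD1 may lower the basal interferon response in these cells, as a hypothesis found and tested on the same data; a clonal difference is equally open, and the list test did not pass with an estimated correlation (adjusted p = 0.19).

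Alisertib effects were smaller in knockout. Noise of genes with few reads does not account for this. The 6042 genes with a mean of at least 1000 had a slope of 0.667 (interval 0.644 to 0.691). A scaling factor moves all genes alike, so it does not account for their ratio of SDs, 0.723 (interval 0.704 to 0.741). Both intervals resampled genes and leave out the spread between libraries. The pattern was not uniform, as stress response genes responded more in knockout (median interaction 0.19). Other lists responded about alike. Medians in knockout and wild type were -0.21 and -0.18 for DNA replication genes and -0.15 and -0.11 for homologous recombination genes. For NF-kB genes they were 0.25 and 0.24. The interaction was called for none of these alike lists. Hypoxia genes stood higher in knockout in DMSO by the preset correlation only (median 0.36) and were not called in alisertib (-0.12). Interferon-stimulated genes stood lower in both treatments, also by the preset correlation only (-0.93 in DMSO and -1.55 in alisertib). Whether the starting level had a part in the smaller effects was not tested. A hypothesis from the slope of 0.667 is that knockout cells take up or respond to the drug less. Lower uptake would not by itself give the larger response of stress response genes. Drug exposure and phosphorylation of Aurora kinase A were not measured.

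Other splits of the libraries were counted. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with as many genes in each of the 4 comparisons: 7893 for alisertib in wild type (highest other split 0), 5834 in knockout (1), 9754 for genotype in DMSO (0) and 9385 in alisertib (0). For the interaction 100 of the 200 splits were counted: the real one, the exchange of genotype labels in 1 treatment only, which was always included, and 98 drawn at random. Of these 10 gave at least 2107 genes, so the count does not exclude chance. It is no fair measure of chance, however: the 9 besides the real one exchanged labels in at least 2 more pairs of libraries in 1 treatment than in the other, which carries the genotype difference into the interaction and points to the structure of the samples. The full exchange gave 11195 genes and the highest of the rest 4088, while the 43 splits with equal exchange in both treatments gave 0. Those 43 mixed knockout and wild-type libraries within groups, which puts the genotype difference into the spread. A count of 0 would be found there with or without an interaction, so those splits do not measure chance either. When the residuals of a fit with additive genotype and treatment effects were reassigned among libraries, the real assignment was the 1 of 100 with as many genes, and the highest other gave 282.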

How the results depend on the processing

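Local centring, the removal of genes in shifted regions and the CHD family list without CHD1 were chosen after seeing the data; the other alternatives were set before. Apart from the settings named below, every count of called genes stayed within 1.5 times its value: 6180 to 8174 for alisertib in wild type, 4171 to 6019 in knockout, 8126 to 9860 for genotype in DMSO, 7720 to 9727 in alisertib and 1542 to 2205 for the interaction. Requiring a 2-fold change left 707, 280, 1710, 1589 and 129 genes, since fewer changes are that large. The interaction passed for 1093 genes at an adjusted p below 0.01 and for 885 without trended variance; the cause of the second was not tested. CHD1 in knockout against wild type in DMSO ranged from -1.77 to -1.66. Of the genes called by limma, edgeR called 95.1% to 98.8% and DESeq2 86.2% to 92.7%, by comparison. The numbers of the replicates do not pair the samples (residual correlations of like-numbered libraries between -0.044 and 0.033), and a replicate block gave 7947, 5885, 9780, 9416 and 2159 genes. A fit on the 6 compared libraries alone has no counterpart for the interaction. A gene called only in 1 treatment or genotype is not shown to differ without the interaction.

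The correlation of alisertib effects was 0.65 with a pseudocount of 5 and 0.55 without a filter. Among genes with a mean of at least 50 it was 0.75. In edgeR it was 0.52 without a filter and 0.64 with a mean of at least 10 reads. DESeq2, which was also run without a filter, gave 0.52. The correlation thus rose as genes with few reads were left out or shrunk. Leaving out 1 library gave 0.57 to 0.60. The set test passed for 55 of 105 lists and comparisons, for 20 with an estimated correlation and for 84 with fry, which does not compare a list with other genes.

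Of 471 results for named genes, 411 kept direction and side of the threshold in every alternative that tested them. At least 1 alternative ended the call of 49, turned 10 and gave 1 a call. Of the 55 called lists, 35 lost their call with the estimated correlation, and the other 20 kept it in every alternative that tested them. Local centring turned AURKA (-0.21 in DMSO, -0.27 in alisertib), XRCC3 (-0.090 in DMSO, -0.061 in alisertib), ATM in DMSO (-0.046), and HMGCS1 (-0.43) and ATP6V0D1 (0.0072) in alisertib, because it subtracts the median of neighbouring genes. AURKA, not called for alisertib or the interaction, turned with median centring (-0.035 in wild type, -0.013 in knockout, 0.022 for the interaction). Its interaction also turned with TMM scaling (0.0088) and edgeR without a filter (0.0075). Its knockout effect ran from -0.017 without knockout DMSO replicate 1 to 0.039 without replicate 2, and its interaction from -0.039 to 0.017 on the same removals. Its interaction turned too without knockout alisertib replicate 1 (9.5e-05), knockout DMSO replicate 3 (0.0011) and wild-type alisertib replicates 1 (0.0066) and 2 (8.9e-05). The cause of these small turns was not tested.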

Other observations

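Some marker genes differed without their lists being called. In knockout against wild type in DMSO, the myeloid marker CD14 read 101 ± 17.1 and 238 ± 10.6. The neuroendocrine marker UCHL1 read 86.5 ± 16.2 and 309 ± 29.5, and FOXA2 19.1 ± 4.05 and 58.7 ± 19.2.

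Regulators of cell death moved in both directions. Under alisertib in knockout BMF went from 204 ± 8.84 to 462 ± 34.8 and BBC3, the gene of the p53-induced protein PUMA, from 117 ± 21.2 to 228 ± 22.7, while the survival gene BCL2L1 went from 13495 ± 296 to 10748 ± 222. Between genotypes in DMSO, BIK, which encodes a pro-apoptotic protein, read 576 ± 48.8 in wild type and 289 ± 19.01 in knockout, and BCL2L11, the gene of BIM, 1034 ± 32.5 and 1383 ± 47.7. The autophagy gene GABARAPL1 rose under alisertib in both genotypes, from 597 ± 27.4 to 1128 ± 42.3 in wild type and from 596 ± 18.7 to 1141 ± 2.00 in knockout.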
